A study of Mus musculus with 6 samples.

How the data were processed

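RNA was measured by bulk sequencing in 6 libraries of Ly6C+ CD115+ bone marrow monocytes from individual C57BL/6 mice: 2 controls, 2 CMML mice with cachexia and 2 CMML mice without cachexia. The groups were taken from the labels. The authors deposited a single table of counts per gene, with 1 column for each library and Ensembl gene identifiers in the rows; the values are whole numbers that were not normalized. Per the submitters' processing notes, which name tools with no role or order, bcl2fastq, CASAVA 1.8 and kallisto were used with the mouse build mm10. Kallisto gives estimated counts, and whether the deposited counts were rounded from such estimates is not given in the sources used here, nor are the annotation release, the use of strand and any filter. A tool that assigns reads among transcripts by estimate can split reads between near-identical genes, so counts of such genes are less certain than their size alone would give.

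The table held 28339 genes, of which 8692 had 0 counts in all libraries. Gene symbols and positions were taken from the GENCODE M21 annotation of GRCm38 (the assembly also called mm10), which matched 26940 identifiers (95.1%); the other 1399 kept their identifier. Total counts per library ran from 19839792 to 24706970, so 1 count was worth 0.0405 to 0.0504 CPM. Mitochondrial genes held 1.79% to 2.69% of counts and the most abundant gene 0.896% to 1.36%. Intervals and floors cover counting error only.

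Counts were analysed in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, filterByExpr on the groups, 13440 genes kept), with all 6 libraries in 1 fit of 3 group means, which left 3 residual degrees of freedom. The common biological coefficient of variation was 0.285. Every adjusted p of a gene is from this test with Benjamini-Hochberg adjustment over the 13440 genes, and a gene is called at an adjusted p under 0.05. Standard errors (SE) of log2 changes are the log2 change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. The contrasts were each CMML group against control, the mean of both CMML groups against control, and CMML with against CMML without cachexia. Where all libraries of a group had 0 counts, a fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with an exact 95% binomial interval, conditional on the summed counts of both groups.

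Of 37 gene lists fixed before the data were examined, 35 were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; the sort markers and sex-linked genes were only looked up. Each list was also tested with a correlation estimated from the data, and with fry, which asks whether a list's genes move, on balance, in 1 direction and does not compare the list with other genes. The form with an estimated correlation also rests on the 3 residual degrees of freedom of the fit, which the preset form does not. A call lost in that form can therefore come from the few libraries as well as from correlation between genes. Phrases such as "adjusted over the list alone" mean Benjamini-Hochberg adjustment of the edgeR p-values over the members of that list.

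The genes named in the text follow a rule set before the data were examined: the sort markers Ly6c1, Ly6c2 and Csf1r, and then 3 parts. Among genes with an adjusted p under 0.05, a log2 change of at least 1, a mean of at least 10 CPM in the higher group and libraries that do not overlap between groups, the 10 with the largest rise and the 10 with the largest fall, leaving out provisional names and sex-linked genes, were taken. So were up to 4 members of a reported list, those past the test with the largest change, or the 2 most abundant where fewer than 2 passed. Where no gene passed, the 5 of lowest p were taken. Not every gene that the rule allows is named, and some are withheld and not reported here. Nup98, Kat7, Mecom and Gm10288, and the list of stromal and endothelial genes were chosen after the values were seen.

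The fitting code was tested on simulated data: negative binomial counts for 13178 genes with 200 genes changed by known folds. For CMML with against CMML without cachexia, 26.0% of 2-fold, 92.0% of 4-fold, 96.0% of 8-fold and 100.0% of 16-fold changes were called in the right direction, with 12 unchanged genes called. For CMML with cachexia against control the shares were 22.0%, 92.0%, 100.0% and 100.0%, with 15 unchanged genes called. In the same simulated counts, CMML without cachexia against control held no changes, and 0 genes outside the 200 were called. Calls among the 200 were not counted there. The simulated spread was that of the fit and did not include differences between mice beyond it. The changed genes had a mean of at least 10 CPM. In the real data Arrdc4 differed by 5.99 on the log2 scale between the CMML groups and did not pass (edgeR adjusted p = 0.0962). These shares therefore do not give the power of the real comparison.

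Alternatives chosen before the data were examined were RLE scaling in edgeR, library size alone, no filter (at least 1 count), a strict filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, a robust prior of the spread, a fit of only the groups compared, a block of replicate number, a minimum of 2-fold, and leaving out each library in turn. When a library is left out its group has 1 library, which is then assumed to vary like the other groups. Replicate numbers come from the labels and name individual mice. Replicates differed by more than sampling noise in each group (chi-square per degree of freedom 26.5, 86.6 and 101), so no library was counted as a duplicate. The overlap of the CMML groups was compared with 20 simulations without changes. All libraries, controls included, were drawn from 1 mean per gene, and both simulated CMML groups were set against the same simulated controls. Names of batches or days are not given in the labels, so no batch was tested.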

Results

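Bulk RNA sequencing measured gene expression in inflammatory monocytes, the Ly6C-high monocytes of the bone marrow, which were sorted by flow cytometry as Ly6C+ CD115+ cells from C57BL/6 mice. The 6 libraries fell into 3 groups of 2: control mice, mice with chronic myelomonocytic leukemia (CMML, a blood cancer of the monocyte lineage) and cachexia (a wasting of body mass that accompanies some cancers), and CMML mice without cachexia. Each library came from an individual mouse per the labels, so the replicates are separate animals. Total counts were 19839792 and 22448810 in the controls, 24706970 and 24156358 in CMML with cachexia, and 23972135 and 24581650 in CMML without cachexia. At this depth, 3 counts in a library corresponded to 0.121 to 0.151 CPM (counts of a gene scaled to a common library total), and 13440 genes passed the filter on low counts.

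The sorted cells carried the transcripts of the markers they were selected on. Ly6c2, which encodes a Ly6C antigen, stood at 1663 ± 299 CPM (SD, n = 2) in controls, 1436 ± 54.8 (n = 2) in CMML with cachexia and 2057 ± 220 (n = 2) in CMML without cachexia. Csf1r, which encodes CD115, stood at 631 ± 84.0, 583 ± 36.1 and 564 ± 93.2 CPM (SD, n = 2 each). Neither gene passed the test in any comparison. Ly6c1, a near-identical neighbour of Ly6c2, had too few counts to be tested, and counts of the pair are uncertain because reads can be split between them. The list of 16 classical monocyte genes passed in no comparison either. Its mean log2 CPM was 8.46 in replicate 2 of CMML without cachexia and 9.36 to 9.59 in the other libraries, so that library stood apart from its group. On the first principal component of log2 CPM, which held 52.2% of the variance, the controls lay at -69.8 and -71.0, CMML with cachexia at 27.8 and 39.8, and replicates 1 and 2 of CMML without cachexia at 5.38 and 67.8. Replicate 1 of that group correlated with the controls at 0.952 and 0.956 (log2 CPM over genes) and with its own replicate at 0.956, so replicate 1 too stood apart within its group. It correlated most with the libraries with cachexia, at 0.965 and 0.959. Replicate 2 correlated with those at 0.959 and 0.951. Each library without cachexia was thus closer to replicate 1 with cachexia than to the other library of its own group.

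The first comparison set all 4 CMML libraries against the 2 controls and asked how monocytes of leukemic mice differ from those of healthy ones. Homeobox genes of the Hoxa cluster rose from near background. Hoxa9, a transcription factor of early blood progenitors, went from 1.40 ± 1.40 CPM (SD, n = 2) to 96.4 ± 21.3 (n = 4). This was a log2 change of 6.12 ± 0.68 (SE). Eya1, which encodes a transcription coactivator of development, and Ikzf2, an Ikaros-family factor, rose with them. In the other direction, a set of genes that the controls expressed at moderate levels kept less than 3% of that level on average in CMML, among them Dock1, a regulator of Rac in engulfment and migration. Immediate early genes such as Fos and Fosb, hemoglobin transcripts and the prostaglandin synthase gene Ptgs2 also fell. In all, 233 genes changed (61 rose, 172 fell; adjusted p under 0.05).

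Among the genes that rose, Hoxa10 (chromosome 6, 52231197 to 52240854, GRCm38) had 0 counts in both controls and 55.6 ± 32.8 CPM in CMML (SD, n = 4), at least 788-fold higher against a floor of 3 counts over the group (adjusted p = 0.0334). Its neighbours Hoxa9 (chromosome 6, 52223100 to 52231089, adjusted p = 0.0199), Hoxa7 (2.36 ± 1.21 to 43.1 ± 9.03 CPM, adjusted p = 0.0171) and Hoxa5 (0.309 ± 0.114 to 11.4 ± 1.78 CPM, adjusted p = 0.0129) lie within the same cluster. Eya1 rose from 0.625 ± 0.495 to 48.2 ± 10.99 CPM (adjusted p = 0.0129) and Ikzf2 from 1.87 ± 0.785 to 62.5 ± 20.6 CPM (adjusted p = 0.0163). Shisa2, Gpr174 and Ly6k rose too, with log2 changes of 5.39 ± 0.76, 6.67 ± 1.05 and 6.92 ± 0.9999 (SE). Of 16 measured stem and progenitor cell genes, 4 rose, all of them Hoxa genes, and 12 did not pass; adjusted over the list alone, 10 rose. The list as a whole was higher in CMML (median log2 change 1.35, camera adjusted p = 2.71e-07, adjusted p = 0.513 with an estimated correlation).

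**Figure D1:**
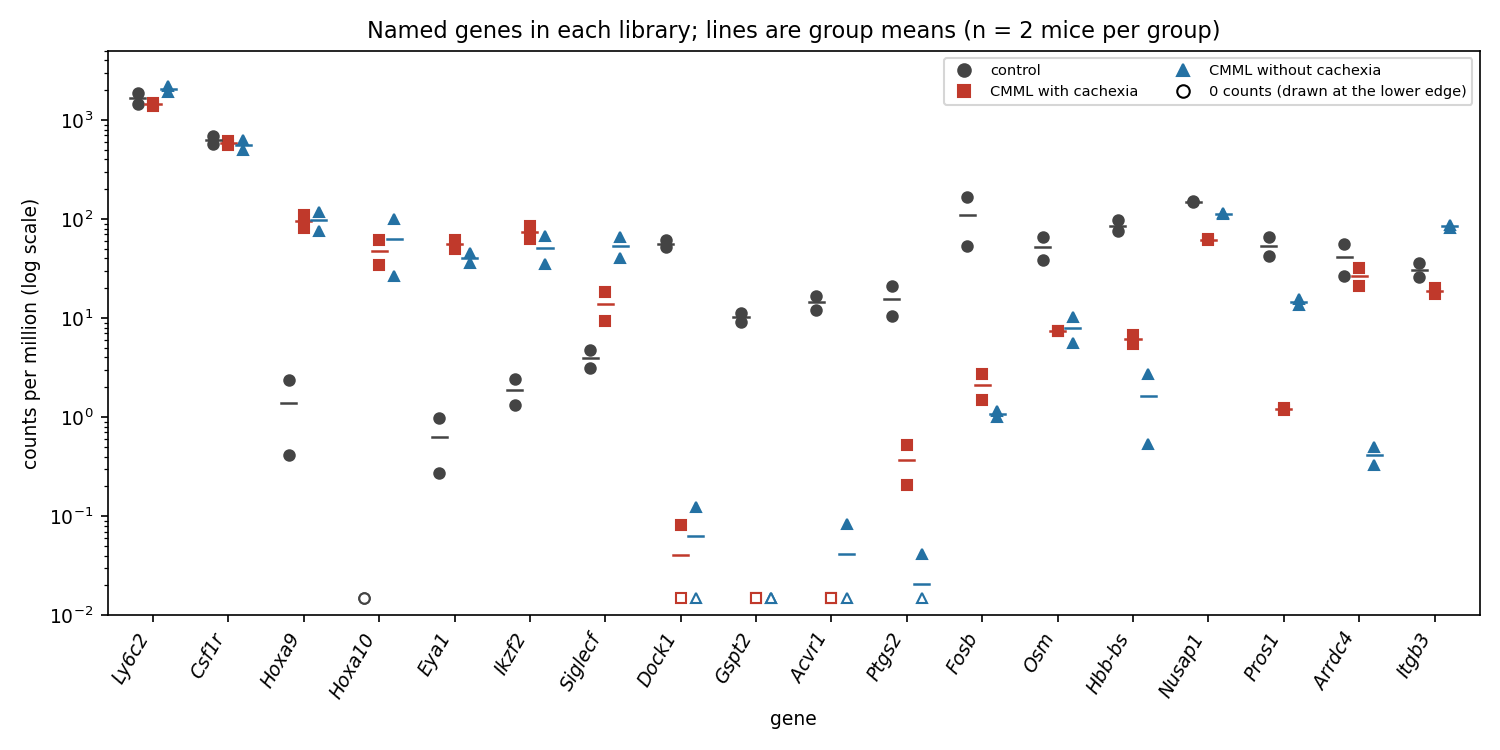
CPM (log scale) of named genes in each of the 6 libraries, with short lines at the group means (n = 2 mice per group); open symbols mark libraries with 0 counts and are drawn at the lower edge. Hoxa10 had 0 counts in both controls and Gspt2 had 0 counts in all 4 CMML libraries, while the sort markers Ly6c2 and Csf1r lay at similar levels in the 3 groups.

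Of the 172 genes that fell, 14 were expressed at 10.2 to 109 CPM in the controls and kept less than 3% of that on average over the CMML libraries. Single libraries could keep more: Sestd1 had 88 counts (3.67 CPM) in replicate 2 of CMML with cachexia. Gspt2, a translation termination factor gene (chromosome X, 94636069 to 94643244), had 0 counts in the 4 CMML libraries against 10.2 ± 1.52 CPM in controls (SD, n = 2), at least 330.5-fold lower (adjusted p = 0.0171). Dock1 (chromosome 7, 134670654 to 135173639) went from 56.6 ± 6.78 to 0.0514 ± 0.0620 CPM (n = 2 and 4, adjusted p = 0.0129). Acvr1, a receptor of bone morphogenetic proteins, had 2 counts in CMML, a ratio of 703 with a 95% counting interval of 194 to 5822. Ica1 had 3 counts, a ratio of 364 with an interval of 124 to 1772. Ccdc91, Sestd1, Smo (the Hedgehog signal transducer) and Agpat4 fell as well, with log2 changes of -8.09 ± 0.76, -7.03 ± 0.91, -6.71 ± 0.53 and -6.33 ± 0.52 (SE). The 14 genes lay on 8 chromosomes, and the spans of 7 of them, introns included, overlap that of another annotated gene on either strand. Whether these pairs share transcript sequence was not examined, so it is not known whether their reads can be confused. The counts of Gspt2 are also uncertain because it is a close copy of another gene.

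Some members of several lists of related genes fell in CMML, and each of these list calls was lost with an estimated correlation. Of 25 immediate early and handling stress genes, 7 fell and 18 did not pass (14 fell adjusted over the list alone). Fosb went from 109 ± 79.1 to 1.60 ± 0.797 CPM, Fos from 803 ± 279 to 64.7 ± 36.8, and Atf3 and Nr4a2 fell by 4.20 and 3.56 on the log2 scale. The list passed with camera adjusted p = 4.28e-08 and lost the call with adjusted p = 0.794 with an estimated correlation. Of 20 NF-kB target genes 2 fell, Ptgs2 (15.7 ± 7.41 to 0.194 ± 0.239 CPM) and Nfkbiz (70.9 ± 1.27 to 16.5 ± 3.73 CPM), 3 adjusted over the list alone (camera adjusted p = 0.000540, adjusted p = 0.794 with an estimated correlation). Of 22 genes of sterol synthesis, 2 fell, among them Stard4, a sterol carrier, from 53.3 ± 0.456 to 24.2 ± 11.2 CPM (3 fell adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.794 with an estimated correlation). Of 11 measured secreted factors linked to cachexia, 1 passed, Osm, which encodes oncostatin M. It fell from 52.1 ± 19.7 to 7.70 ± 1.96 CPM (2 fell adjusted over the list alone, camera adjusted p = 0.0178, adjusted p = 0.794 with an estimated correlation).

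Dividing-cell genes were also lower in CMML. Of 35 mitosis genes 4 fell, Nusap1, Kif15, Bub1 and Cdca3, each by 0.70 to 0.86 on the log2 scale, and 32 fell adjusted over the list alone (camera adjusted p = 2.50e-15, adjusted p = 0.513 with an estimated correlation). Of 31 DNA replication genes 1 fell, Rrm2, a subunit of ribonucleotide reductase (264 ± 11.2 to 157 ± 49.7 CPM), and 8 fell adjusted over the list alone (camera adjusted p = 2.05e-07, adjusted p = 0.794 with an estimated correlation). The 38 type I interferon response genes were lower in the fitted change in each case (median log2 change -1.39, camera adjusted p = 6.70e-09, adjusted p = 0.794 with an estimated correlation). As single genes 0 passed, over all genes or adjusted over the list alone. The controls themselves differed on this list, at mean log2 CPM of 4.64 and 5.77, and replicate 1 of CMML without cachexia, at 4.81, lay between them. Ribosomal protein genes (median log2 change 0.18, camera adjusted p = 0.00510) and glycolysis genes (median 0.28, camera adjusted p = 0.00885) were slightly higher as lists, both with adjusted p = 0.794 with an estimated correlation. For the ribosomal list, only replicate 2 of each CMML group (mean log2 CPM 9.30 and 9.21) lay above both controls (8.72 and 8.89). Its mean difference of 0.19 was 0.08 and 0.07 without the one or the other of these libraries, and 0.11 without control replicate 1, and the call was lost in each case. In the glycolysis list the 1 member that passed, Vegfa, fell, from 23.3 ± 1.799 to 9.29 ± 1.15 CPM. It encodes a growth factor for blood vessels.

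Markers of other cells of the marrow moved with these groups. Of 11 erythroid genes, 6 fell, among them Slc4a1, Hbb-bs (86.0 ± 15.2 to 3.87 ± 2.80 CPM) and Hba-a2 (60.3 ± 17.3 to 2.77 ± 1.88 CPM), and 8 fell adjusted over the list alone (camera adjusted p = 1.43e-09, adjusted p = 0.513 with an estimated correlation). Counts of the hemoglobin genes are uncertain because near-identical copies share reads. The list of neutrophil secondary and tertiary granule genes was lower (median log2 change -1.22, camera adjusted p = 0.00150, adjusted p = 0.794 with an estimated correlation), with 0 of 20 members past the test and 2 adjusted over the list alone. Its members S100a9 (3574 ± 1158 CPM in controls, 914 ± 785 in CMML; adjusted p = 0.211) and Ngp (3051 ± 1053 and 879 ± 759 CPM, adjusted p = 0.264) varied widely within groups.

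With an estimated correlation 0 of the 35 lists passed (camera; 3 at an unadjusted p under 0.05), and with the self-contained test fry 3 did, the mitosis, erythroid and progenitor lists (adjusted p = 0.0236 each). The count of 233 genes fell to 0 without either control library or without replicate 2 of CMML with cachexia (1282 to 2239 genes at an unadjusted p under 0.05). It was 93 without replicate 1 of that group and 860 without replicate 1 of CMML without cachexia. It was 375 with no filter, 106 with a strict filter and 1215 with DESeq2.

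Each CMML group was then set against the same controls. In CMML with cachexia 119 genes changed (45 rose, 74 fell). Eya1, near background in controls (0.625 ± 0.495 CPM, SD, n = 2), reached 56.1 ± 8.41 CPM (n = 2; log2 change 6.49 ± 0.51 SE, adjusted p = 0.0270). Col19a1, a collagen gene, rose from 2 counts to 13.01 ± 4.67 CPM, a ratio of 276 with a 95% counting interval of 76.2 to 2288. Hoxa10 (at least 681-fold higher; adjusted p = 0.0475) and Hoxa9 (log2 change 6.11 ± 0.70 SE, adjusted p = 0.0354) rose as well. Pros1, which encodes the anticoagulant protein S, fell from 53.7 ± 16.6 to 1.21 ± 0.0536 CPM (adjusted p = 0.0199), and Slc36a4, an amino acid transporter gene, from 46.2 ± 8.36 to 1.03 ± 0.0789 CPM (adjusted p = 0.0270).

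Cell division genes were lower in this group. All 35 mitosis genes had a negative fitted change, 10 of them past the test and 33 adjusted over the list alone, and the list passed in camera (median log2 change -0.86; adjusted p = 8.79e-22, adjusted p = 0.485 with an estimated correlation) and in fry (adjusted p = 0.0202). Nusap1 went from 150 ± 0.912 to 61.7 ± 0.926 CPM (adjusted p = 0.0270), and Kif15, Bub1 and Kif23 fell by 1.26, 1.16 and 1.08 on the log2 scale. Rrm2 was the 1 of 31 DNA replication genes that fell (18 adjusted over the list alone; adjusted p = 3.76e-11 in camera, adjusted p = 0.825 with an estimated correlation). Of 16 p53 target genes 1 rose, Trp53inp1, a stress-induced nuclear protein gene (34.5 ± 1.88 to 134 ± 14.2 CPM, adjusted p = 0.0403), 2 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.825 with an estimated correlation). Osm fell by 2.81 on the log2 scale (adjusted p = 0.0481), the 1 member of 11 in its list to pass (2 adjusted over the list alone, camera adjusted p = 0.0170, adjusted p = 0.825 with an estimated correlation). The 38 type I interferon genes were all lower in the fitted change, with 0 past the test either way (median -1.72, camera adjusted p = 4.21e-11, adjusted p = 0.825 with an estimated correlation). Erythroid genes were lower here too (median log2 change -3.58, 2 of 11 fell, 9 adjusted over the list alone, camera adjusted p = 3.45e-08, adjusted p = 0.653 with an estimated correlation). In all 11 lists passed, 3 higher and 8 lower, and 0 of them with an estimated correlation.

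In CMML without cachexia 65 genes changed (24 rose, 41 fell). Hoxa9 (adjusted p = 0.0424) and Eya1 (adjusted p = 0.0294) rose to 97.1 ± 30.6 and 40.4 ± 6.61 CPM (SD, n = 2 each). Siglecf, a sialic acid receptor gene of eosinophils and macrophages, rose from 3.92 ± 1.13 to 53.3 ± 18.7 CPM (adjusted p = 0.0462), and Tespa1 from 2.15 ± 0.963 to 24.2 ± 7.47. Cracr2b, a regulator of calcium entry, rose from 5.90 ± 2.34 to 44.3 ± 4.78 CPM and Chdh, a choline dehydrogenase gene, from 53.6 ± 4.11 to 205 ± 4.26 CPM. Arrdc4, an arrestin-domain gene, fell from 41.3 ± 20.4 to 0.413 ± 0.122 CPM (adjusted p = 0.0294) and Rnf217 from 16.5 ± 4.67 to 0.0832 ± 0.118 CPM (adjusted p = 0.0433). Ptgs2 was left with 1 count, a ratio of 755 with a 95% counting interval of 135 to 29846.5. Of 11 erythroid genes 5 fell, including Hbb-bs and Slc4a1 (8 adjusted over the list alone, camera adjusted p = 1.31e-10, adjusted p = 0.650 with an estimated correlation). The ferroportin gene Slc40a1 was the 1 of 16 tissue macrophage genes that fell (17.0 ± 7.03 to 0.249 ± 0.236 CPM; 2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0474, adjusted p = 0.680 with an estimated correlation). The summed CPM of the macrophage list was nonetheless above the controls (350 and 354 against 280 and 322). The mitosis list passed with a smaller change than in the other group (median log2 change -0.26, camera adjusted p = 6.48e-05, adjusted p = 0.667 with an estimated correlation), and 0 of its 35 members passed, over all genes or adjusted over the list alone. Immediate early and handling stress genes were lower (24 of 25 in the fitted change, 1 past the test, 13 adjusted over the list alone, camera adjusted p = 5.23e-10, adjusted p = 0.667 with an estimated correlation). So were neutrophil secondary and tertiary granule genes (19 of 20, median log2 change -1.78, 0 past the test either way, camera adjusted p = 2.37e-05, adjusted p = 0.688 with an estimated correlation). In all 13 lists passed, 3 higher and 10 lower, and 0 of them with an estimated correlation.

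The 2 CMML groups shared 47 of these calls, 22 higher and 25 lower, and 0 genes were called in opposite directions. Independent lists of these sizes would share 0.0804 higher and 0.226 lower genes. In 20 simulations without changes, all libraries, controls included, were drawn anew, and the 2 simulated CMML groups shared at most 1 gene in any run. Data without changes give few calls to share, so this count does not show how much of the 47 comes from the real controls. The covariance of the log2 changes over genes was 0.744, against 0.128 in the simulated groups, a difference of 0.616, while the correlation was 0.777 against 0.505. Because the controls could not be split into sets of 2 libraries, part of the excess over these values can come from the shared controls. Without any 1 of the controls, of the libraries with cachexia or of replicate 2 of CMML without cachexia, 0 genes were shared, and 223 were shared without replicate 1 of CMML without cachexia.

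With an estimated correlation 0 lists passed in either group (camera; 2 at an unadjusted p under 0.05 in each), and fry called 2 lists with cachexia, mitosis and progenitor, and 0 without (lowest adjusted p = 0.0609). The count of 119 was 0 without either control or either library with cachexia (1273 to 2478 genes at an unadjusted p under 0.05). It was 447 and 457 without replicates 1 and 2 of CMML without cachexia, 524 with only the groups compared, 247 with limma-voom and 1233 with DESeq2. The count of 65 was 0 without either control, without either library with cachexia, without replicate 2 of CMML without cachexia or with only the groups compared (902 to 1928 genes at an unadjusted p under 0.05). It was 468 without replicate 1 of that group, and 739 with DESeq2.

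The last comparison, CMML with cachexia against CMML without it, addressed what accompanies wasting among leukemic mice. Cell division genes were lower with cachexia. The 35 mitosis genes averaged a log2 CPM of 6.31 and 6.20 in the libraries with cachexia, 6.89 and 6.91 in those without, and 7.20 and 7.08 in the controls. All 35 had a negative fitted change, with a median of -0.69. Genes of tissue macrophages, neutrophil granules and red cells, and glucocorticoid-responsive genes, were higher as lists with cachexia than without it. These list calls and that of the mitosis genes were lost with an estimated correlation (adjusted p = 0.688 to 0.939). The difference of the neutrophil list went from 0.88 to 0.03 without 1 library. The mean log2 CPM of the red cell list lay below both controls in every CMML library. For macrophage genes it did so in both libraries without cachexia and in replicate 2 with cachexia. The summed CPM of the macrophage genes, in contrast, lay above both controls in every CMML library. For single genes 0 of 13440 passed with edgeR (1157 at an unadjusted p under 0.05, where chance gives 672; lowest adjusted p = 0.0640) and 0 with limma-voom, while DESeq2 called 316 (157 higher, 159 lower).

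Of the 35 mitosis genes 0 passed over all genes and 32 fell adjusted over the list alone (camera adjusted p = 1.58e-26, adjusted p = 0.688 with an estimated correlation, fry adjusted p = 0.0528). The proliferation marker Mki67 stood at 441 ± 52.5 CPM with and 765 ± 172 without cachexia (SD, n = 2 each; adjusted p = 0.421), and Top2a, a topoisomerase gene, at 432 ± 19.3 and 727 ± 0.925 (adjusted p = 0.318). Of 31 DNA replication genes 7 fell adjusted over the list alone and 0 over all genes (median log2 change -0.39, camera adjusted p = 1.34e-12, adjusted p = 0.688 with an estimated correlation), and Pcna, the replication clamp gene, stood at 262 ± 8.01 and 373 ± 45.9 CPM. Of the 38 type I interferon genes, 37 were lower in the fitted change and 0 passed, over all genes or adjusted over the list alone (median -0.92, camera adjusted p = 7.61e-06, adjusted p = 0.939 with an estimated correlation). The difference in this list, -0.78 in mean log2 CPM, was -0.04 without replicate 1 of CMML without cachexia, which ended the call.

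**Figure D2:**
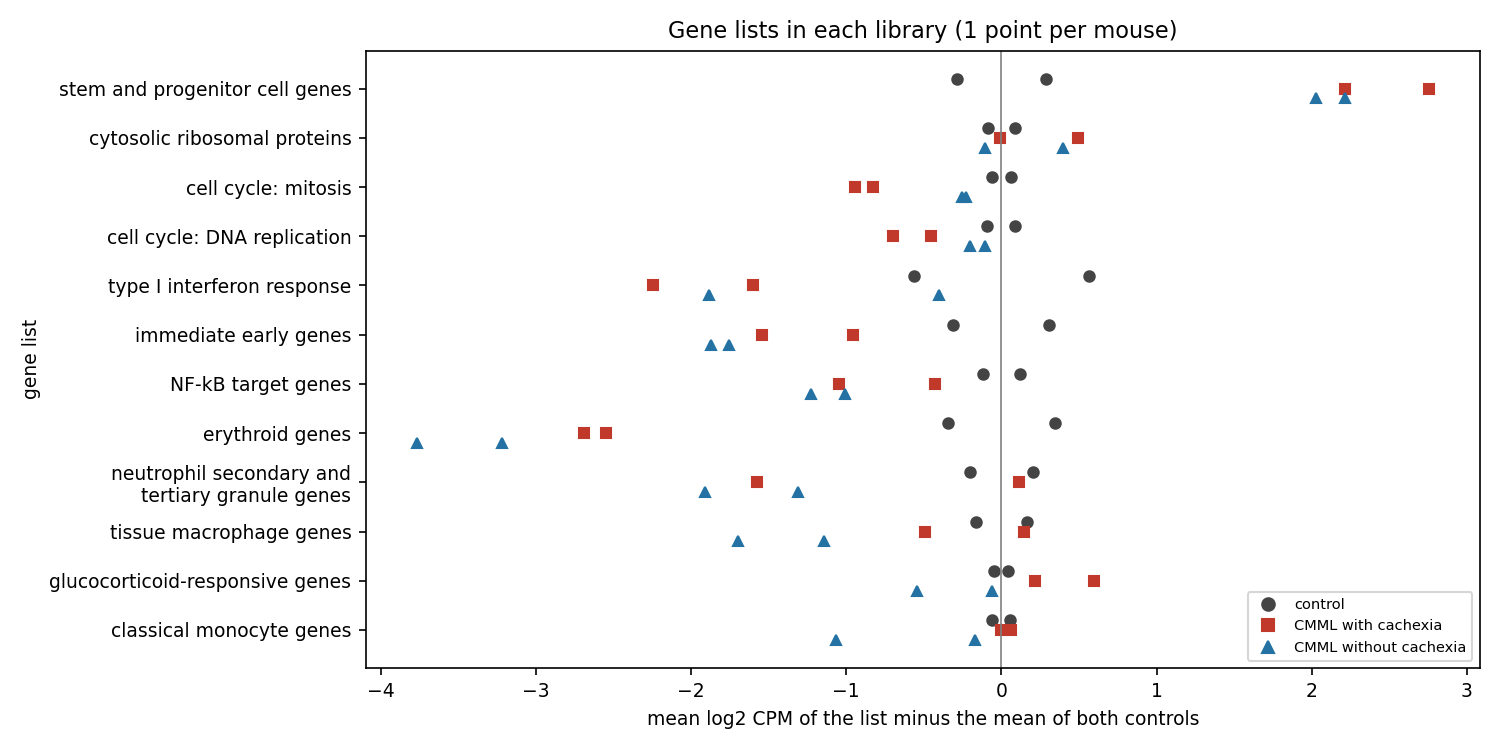
Mean log2 CPM of gene lists in each library, relative to the mean of both controls (vertical line at 0); 1 point per mouse, n = 2 per group. The mitosis list lay lowest in the libraries with cachexia, and the stem and progenitor list lay above both controls in all 4 CMML libraries.

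Higher lists with cachexia held genes of several other cell types. Tissue macrophage genes (16 measured, 4 higher adjusted over the list alone and 0 over all genes; median log2 change 0.98, camera adjusted p = 0.000264, adjusted p = 0.688 with an estimated correlation) included Hmox1, the heme oxygenase gene, at 126 ± 29.4 CPM with and 84.8 ± 15.1 without cachexia. Their most abundant member, Adgre1, which encodes F4/80, stood at 203 ± 9.28 and 225 ± 37.7 CPM. The macrophage list had a mean log2 CPM of 2.32 and 1.69 with cachexia and 1.03 and 0.476 without, against 2.01 and 2.34 in controls. Against control, its median log2 change was -0.04 with cachexia and -1.55 without, so on this scale the difference lay mostly in the group without cachexia. The summed CPM of the list did not show lower levels than in controls. It was 452 and 418 with cachexia and 350 and 354 without, against 280 and 322 in controls, where Adgre1 stood at 121 CPM. Erythroid genes (11 measured, 2 higher adjusted over the list alone and 0 over all genes, camera adjusted p = 0.0133, adjusted p = 0.688 with an estimated correlation) included Hbb-bs at 6.13 ± 0.879 and 1.62 ± 1.54 CPM and Hba-a2 at 4.26 ± 1.16 and 1.28 ± 0.599. Their mean log2 CPM was -0.149 and -0.0114 with cachexia and -0.681 and -1.23 without, against 2.19 and 2.88 in controls. Both CMML groups were thus low in these genes. Neutrophil secondary and tertiary granule genes (20 measured, 0 past the test either way, camera adjusted p = 0.0133, adjusted p = 0.939 with an estimated correlation) included S100a9 at 1200.0 ± 1140.3 and 629 ± 470 CPM. The mean log2 CPM of this list was 7.89 and 6.20 with cachexia and 6.46 and 5.86 without, against 7.57 and 7.97 in controls, so 3 of the 4 CMML libraries lay below both controls. Without replicate 1 of CMML with cachexia the list's mean difference went from 0.88 to 0.03 and its test turned direction. Glucocorticoid-responsive genes (19 measured; median 0.47, camera adjusted p = 0.0243), LXR and PPAR lipid handling genes (26 measured; median 0.25, camera adjusted p = 0.0273) and genes of suppressive myeloid cells (17 measured; median 0.42, camera adjusted p = 0.0454) were each higher, with 0 members past the test either way and adjusted p = 0.688 with an estimated correlation. On leaving out a library in turn, the call was lost in 2 of 6 cases for the erythroid, neutrophil, lipid and glucocorticoid lists and in 5 of 6 for the suppressive myeloid list. Without replicate 2 of CMML without cachexia the mean difference went from 0.71 to 0.47 for the glucocorticoid list, which lost its call, and from 0.55 to 0.36 for the lipid list, which kept it. In the lipid list, Apoe stood at 345 ± 114 CPM with and 83.7 ± 96.3 without cachexia, while Cxcr4 of the glucocorticoid list went against its list (394 ± 51.1 and 614 ± 63.6 CPM).

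The 5 genes of lowest p with a regular name did not pass (adjusted p = 0.0962 each). Pros1 stood at 1.21 ± 0.0536 CPM with and 14.5 ± 1.34 without cachexia (n = 2 each; log2 difference -3.58 ± 0.29 SE), against 53.7 ± 16.6 in controls. Arrdc4 stood at 26.6 ± 7.997 and 0.413 ± 0.122 CPM (5.99 ± 0.54), and Olfml2b, an extracellular matrix gene, at 47.2 ± 8.86 and 6.09 ± 1.15 (2.95 ± 0.26). Itgb3, the integrin beta chain of platelets and macrophages, stood at 18.9 ± 1.62 and 84.3 ± 4.33 (-2.16 ± 0.20). Eps8l1 had 2 counts with cachexia and 12.3 ± 2.28 CPM without, a ratio of 299 with a 95% counting interval of 82.4 to 2473.

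Of 3 further lists that bear on wasting or on the sorted cells, 0 passed in camera. They were the secreted factors linked to cachexia (adjusted p = 0.447), inflammatory cytokines and chemokines (adjusted p = 0.828) and classical monocyte genes (adjusted p = 0.869). Only 11 of 26 secreted factors and 13 of 24 cytokines and chemokines could be tested. The others were left out, mostly for low counts, and nothing is known of them here. The median log2 change was -0.25 for the secreted factors, whose test also pointed lower while their mean difference was 0.15, and -0.04 for the classical monocyte genes, whose test and mean difference (0.65) pointed higher. Among their abundant members, Lcn2 stood at 611 ± 481 CPM with and 202 ± 107 without cachexia, and Tgfb1 at 343 ± 10.1 and 489 ± 91.1. The chemokine gene Ccl9 stood at 422 ± 67.2 and 348 ± 169 CPM, and Ccl6 at 313 ± 183 and 240 ± 96.2. The fibronectin gene Fn1 stood at 8410 ± 481 and 2085 ± 2096 CPM. With an estimated correlation 0 of the 35 lists passed (1 at an unadjusted p under 0.05), and with fry 0. The count of single genes was 7 with no filter, 1 with a strict filter, 1 with a robust prior of the spread and 10 without replicate 1 of CMML without cachexia.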

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

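Tests of another cell type, of an altered stretch of the genome, of handling, of a single library and of promyelocyte-like cells were chosen after the result was seen; those of overlapping genes and of GC content were not. The tests of another cell type and of handling, with their bounds, replaced earlier forms whose outcomes had been seen. The earlier forms had argued against another cell type and for handling, so the open outcomes below come from a changed test.

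In 4 genes and 1 list that the text names, both libraries of 1 CMML group lay above both controls and both libraries of the other lay below. Olfml2b was higher with cachexia (log2 difference 2.95; 53.5 and 40.9 CPM, against 21.9 and 28.8 in controls and 6.91 and 5.28 without cachexia). Fn1 was higher too (2.01; 8070 and 8750 CPM, against 5369 and 3949, and 3567 and 603). Itgb3 was lower (-2.16; 19.997 and 17.7 CPM, against 25.7 and 35.8, and 87.4 and 81.2), as was Eps8l1 (-8.05; 0.0810 and 0 CPM, against 6.24 and 7.78, and 13.9 and 10.7). The mean of the glucocorticoid-responsive genes was higher (0.71; mean log2 CPM 6.01 and 5.63, against 5.46 and 5.37, and 5.36 and 4.87), but replicate 1 without cachexia lay barely below control replicate 2 and the call of this list was lost with an estimated correlation (adjusted p = 0.688). The opposite movement itself was not tested. Over all 13440 genes, 297 (2.21%) showed this arrangement, where chance ordering of 6 libraries gives 2.22%. That chance figure treats all 6 libraries as alike, but in 30.4% of genes the controls did not overlap the CMML libraries. The share therefore does not decide whether such genes are in excess.

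The genes that kept less than 3% of their control level on average in CMML numbered 14, and 1 of them, Sestd1, had 88 counts in a single CMML library. Among them were the immediate early gene Fosb (165 and 53.3 CPM in control replicates 1 and 2) and the NF-kB target gene Ptgs2. Handling, which is left open below for immediate early genes, was not tested for this set. A move of most reads to 1 overlapping gene is argued against: 0 of the 14 overlap a measured gene that gained as much as 50% of the lost CPM. Smaller gains, or gains split over several genes, were not tested. A single altered stretch of the genome is also argued against, since 0 of the 14 lay within 5 Mb of another, where 10000 random lists of 14 genes of similar level had a median of 0. Cells of another type in the control sorts stay open, although a Ly6C+ CD115+ gate is meant to leave out red cell precursors. The lists of other types that fell 8-fold or more, which was the erythroid list alone (median -4.54 over its 4 members of at least 10 CPM; Hbb-bs at 86.0 CPM), summed to 58.0% of the CPM of the 14 genes in controls, between the bounds for (all of that CPM) and against (50% of it), which were set after the earlier form was seen. That form asked for a list median of -5 or lower, which no list reached. The 14 genes themselves fell by a median of 117-fold, while the quartiles of those 4 erythroid members were -4.71 and -4.36 on the log2 scale. A gene that keeps less than 3% falls more than these quartiles, so the choice of the 14 genes fixed this comparison in advance. No conclusion on red cell precursors follows from it, and it covers no other cell type. A type without a list was not tested; a biological difference of the leukemic cells, which the design confounds with any such difference between the animals, stays open as well.

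Immediate early genes, which respond within minutes to handling of cells, were higher in the controls. For the 23 members with a negative change, the controls differed by a median of 0.566 (absolute log2), more than on 82.4% of the other 34 lists (28 of 34) but less than on the type I interferon list (0.924). In the earlier form of the test, against random lists of single genes of similar level, which unlike these genes are not regulated together, 0.566 exceeded the highest of 10000 (0.440). Handling time that differed between animals may account for part of the difference and cannot be told apart from leukemia, because each library is a separate animal and no handling time is given in the labels.

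Mitosis genes were lower with cachexia. A single library is argued against, since the mean log2 difference closest to 0 on leaving out any library was -0.59. A trend with GC content and transcript length is argued against as the whole cause, because the mean went from -0.64 ± 0.17 to -0.68 ± 0.17 (SD over the 35 genes) after the trend was removed. Fewer promyelocyte-like cells in the sort stay open: the 9 primary granule genes had a median of -0.019 between the CMML groups, with quartiles of -0.32 and 0.07, which decides nothing. That cell division differs with cachexia is a hypothesis from the same 4 libraries, and the call is lost with an estimated correlation.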

How the results depend on the processing

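Settings chosen before the data were examined changed most counts of genes, and the cause was not tested. Leaving out a library also leaves fewer degrees of freedom, but some counts rose when a library was left out. For CMML with cachexia against CMML without, 0 genes became 7 with no filter, 1 with a strict filter, 1 with a robust prior, 316 with DESeq2 and 0 to 10 on leaving out a library. For CMML with cachexia against control, 119 became 253 with no filter, 1233 with DESeq2, 247 with limma-voom, 524 with only the groups compared and 0 to 457 on leaving out a library. For CMML without cachexia against control, 65 became 147, 40 with a strict filter, 739 with DESeq2, 114 with limma-voom, 0 with only the groups compared and 0 to 468 on leaving out a library. For both CMML groups against control, 233 became 375 with no filter, 106 with a strict filter, 1215 with DESeq2 and 0 to 860 on leaving out a library. The overlap of 47 became 452 with DESeq2 and 0 to 223 on leaving out a library. RLE scaling and library size alone kept the count of each of these 4 comparisons within 1.5 times, and RLE scaling gave an overlap of 48. Where a count was 0, between 834 and 2478 genes had an unadjusted p under 0.05.

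A replicate block gave 0, 0, 2 and 85 genes in these 4 comparisons. Replicate numbers did not pair the mice: deviations from group means correlated at 0.00865, -0.0334 and -0.0350 across genes.

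With an estimated correlation the counts of lists, 9, 11, 13 and 12, became 0 each, and with fry 0, 2, 0 and 3. On leaving out a library they ran from 7 to 15, 6 to 14, 10 to 15 and 10 to 14. These counts include lists newly called. Of the 9, 11, 13 and 12 calls, at least 5, 6, 9 and 10 were kept. Between the CMML groups 5 of 9 were kept without replicate 1 with cachexia (7 called) and without replicate 2 without cachexia (11 called). Of 270 leave-one-out values for lists past the test, 39 lost the call and 3 turned. Of 348 values under the other settings, 97 lost it and 0 turned. Calls lost with an estimated correlation did not all come from correlation between genes. Between the CMML groups the lipid list had an estimated correlation of -0.013, below the preset 0.01. Its unadjusted camera p still went from 0.00625 to 0.0551.

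Of 372 leave-one-out values for named genes past the test, 243 lost the call and 0 changed sign. Of 519 values under the other settings, 74 lost it and 0 changed sign. Of 309 such values for named genes not past the test, 14 gained a call, all between the CMML groups, with no filter or DESeq2. Signs turned in some genes not past the test, on leaving out a library. Between the CMML groups, log2 differences ran from -0.11 to 0.22 for Csf1r (-0.028 without replicate 1 with cachexia), -0.69 to 2.01 for S100a9, -0.60 to 2.33 for Ngp, -0.31 to 0.035 for Adgre1, -0.15 to 0.88 for Ccl9 and -0.40 to 0.88 for Ccl6. Against control, Csf1r ran from -0.25 to 0.027 with cachexia and from -0.27 to 0.0066 over both groups, where Ly6c2 ran from -0.13 to 0.25 (-0.0071 without replicate 1 without cachexia) and Lyz2 from -0.57 to 0.13. Lists whose test turned between the CMML groups, by mean difference, were neutrophil granule genes (0.026 to 1.73), secreted factors (-0.31 to 0.52), cytokines (-0.070 to 0.74) and classical monocyte genes (0.20 to 1.09, with 0.60 without replicate 1 with cachexia). The ribosomal list ran from 0.0010 to 0.49 with and from -0.11 to 0.40 without cachexia against control.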

Other observations

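The test of a joined transcript was chosen after the result was seen, and the genes in this part were picked by eye or for their known roles.

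Nup98, which encodes a protein of the nuclear pore, and Kat7, a histone acetyltransferase gene, were both higher in all 4 CMML libraries. Nup98 (chromosome 7, 102119398 to 102210176) rose from 70.5 ± 0.215 CPM (SD, n = 2) to 283 ± 73.8 (n = 4; log2 change 1.98 ± 0.16 SE, adjusted p = 0.0129). Kat7 (chromosome 11, 95274259 to 95310246) rose from 133 ± 9.81 to 525 ± 104 CPM (1.97 ± 0.19 SE, adjusted p = 0.0171). The excess of Kat7 over controls was 1.66, 1.75, 1.91 and 2.21 times that of Nup98 in the 4 CMML libraries. The spread of this ratio (SD of the log2 ratio 0.180) lay at the 4.21st percentile of the 1830 pairs of the 61 genes called higher (median 0.658). A candidate explanation is a transcript that joins sequence of both genes, since NUP98 fusions are known drivers of myeloid leukemia; the labels name no such construct, and the counts hold no junction reads. Genes regulated together would keep a ratio as well, so the test does not separate these readings.

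Mecom, an oncogene of blood progenitors, was highest in a control: 158 CPM (3457 counts) in control replicate 2 and 0.195 CPM (4 counts) in control replicate 1, with 23.7 and 27.9 CPM with cachexia and 2.83 and 0.532 without. Gm10288, a processed pseudogene on chromosome 3, had the lowest p of the comparison of the CMML groups (adjusted p = 0.0640), at 30.6 and 34.2 CPM with cachexia and 2.25 and 2.66 without, against 1.804 and 1.83 in controls; reads of a pseudogene can come from its parent gene.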
